A study of Pseudomonas aeruginosa with 6 samples.

How the data were processed

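RNA was measured by strand-specific RNA sequencing of rRNA-depleted total RNA from 3 wild-type and 3 aceE mutant libraries, per the labels' protocols. The submitters' processing notes name FastQC, fastp 0.23, STAR 2.7.11a, featureCounts 2.0.6 and DESeq2 1.40.2, without settings. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. If counting ignored strand, reads of overlapping and antisense genes would be mixed. The labels' protocols state that rRNA was depleted, and since features carry no type, the share of counts left in rRNA and tRNA was not analysed here.

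The authors deposited raw counts as whole numbers, one column per library and one row per feature. They also deposited a table of normalised values, used here as a signal for a check only. All 34374 of its values equalled the raw count divided by the library's median-of-ratios size factor within 0.1%, so it holds no separate measurement. Every column name matched a single sample title, and 0 columns of per-sample values were left unmapped.

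Features are named only by database identifiers. None of the 5729 identifiers occurred in the gene table used here, which describes P. aeruginosa PAO1, another species. Names were not inferred from the order of the rows. The 27 fixed gene lists, covering central metabolism, amino acid and aromatic compound use, the catabolite repression system, respiration, motility, stress and prophages, were therefore not tested, nor were the level of aceE, the list tests, and the alternative without rRNA and tRNA. The rule for named genes, written before the data were examined, took the features with the largest changes at adjusted p under 0.05, at least 2-fold, with non-overlapping groups and at least 10 counts in every library of the higher group. It planned 10 per direction together with members of the lists and the ends of the longest runs. Only the first 2 per direction are named, because the identifiers carry no gene names.

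Counts were analysed in R 4.3.3 with edgeR 4.0.16. Features with low counts were removed with filterByExpr at its default settings, which left 5480 features and removed 249 that held 0.063% of all counts. Libraries were scaled by TMM, and the group effect was tested with the quasi-likelihood F test in a model with the group alone. The p-values were adjusted by the Benjamini-Hochberg method over all tested features. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Levels are TMM-scaled counts per 1000000 (CPM), given as mean ± SD of 3 libraries. Log2 CPM for components and correlations used a prior count of 2. Runs were counted over consecutive rows of the whole table, an untested feature ending a run. The trend along the rows was the median log2 fold change of the middle 50% of rows minus that of the others, with an interval from 1000 bootstrap draws of blocks of 50 rows.

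The test was tried on simulated data with the real features' means, dispersions and library sizes. Rises and falls were planted in equal number, and libraries were drawn independently, without the deviations that real libraries shared. In 5423 features of the simulated mutant against wild-type comparison, edgeR recovered 98 of 100 features changed 4-fold and 55 of 98 changed 2-fold, and 11 of its 164 calls (6.71%) were false. Many changes of 2-fold or less may therefore go undetected at this spread between libraries and this depth, of 1835938 to 2183468 counts per library. Depth and spread were not varied apart, and the recovery and false-call rates need not hold in the real libraries. Intervals on shares cover counting error only and treat features as independent, although adjacent rows changed together.

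Alternatives fixed before the data were examined were DESeq2 size factors and upper-quartile factors, no filter and a stricter filter of 50 counts in 3 libraries, the replicate number as a block, DESeq2 1.42.0 and limma-voom (limma 3.58.1) in place of edgeR, stricter limits, a test against 2-fold, shorter runs, and each library left out in turn. Total-count scaling, library quality weights, the 5 most abundant features left out, and both libraries that stood apart left out were added after seeing the data. The trend along the rows was also measured only after it was seen in the plot of fold changes by row.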

Results

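RNA sequencing was used to compare the transcriptome of Pseudomonas putida KT2440, a soil bacterium used as a laboratory and biotechnology strain, with that of a derivative in which aceE was inactivated. The aceE gene encodes a component of pyruvate dehydrogenase, the enzyme complex that converts pyruvate to acetyl-CoA. The series title names catabolite repression, the preferential use of some carbon sources over others, as the process of interest. GEO's organism field reads Pseudomonas aeruginosa, whereas the strain label is KT2440 and the design text names P. putida. Both groups held 3 libraries, from cultures grown in rich medium with glucose and harvested in mid-exponential growth. The labels do not state that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

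The count table listed 5729 annotated features under database identifiers. Total counts per library lay between 1835938 (wild-type replicate 1) and 2183468 (mutant replicate 1), and the median feature had between 58 and 84 counts in a library. The 5 most abundant features took 32.6% ± 10.6 of all counts in the wild type and 35.8% ± 5.49 in the mutant (SD, n = 3 each). The files do not pair the identifiers with gene names or positions, and none of them occurred in the gene table used here, so aceE itself and the metabolic pathways were not analysed here. Results are therefore given for sets of features, and 4 identifiers are named.

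The mutant and the wild type differed in 350 of 5480 tested features, of which 286 were higher and 64 lower in the mutant (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). With a limit of 2-fold added, 219 features were higher and 37 lower, so that 85.5% of the changed features had risen (exact binomial 95% interval 80.6 to 89.6%). The interval treats features as independent and leaves out the spread between libraries. With each library left out in turn, the share ran from 75.7% (without mutant replicate 1) to 92.3% (without wild-type replicate 3). All 256 features past both limits had scaled counts (CPM, counts per 1000000 of the scaled library total) that did not overlap between the groups, against 20.3% of all tested features and 10% by chance in a comparison of 3 with 3. Since they were selected on the same libraries, this is a description and no separate evidence. The rises were also larger than the falls. The median of the risen features was a log2 fold change of 1.68, or 3.21-fold, and 84 of them were at least 4-fold and 27 at least 8-fold higher. The fallen features had a median log2 fold change of -1.21, or 2.31-fold, and 7 of them were at least 4-fold and 2 at least 8-fold lower.

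**Figure D1:**
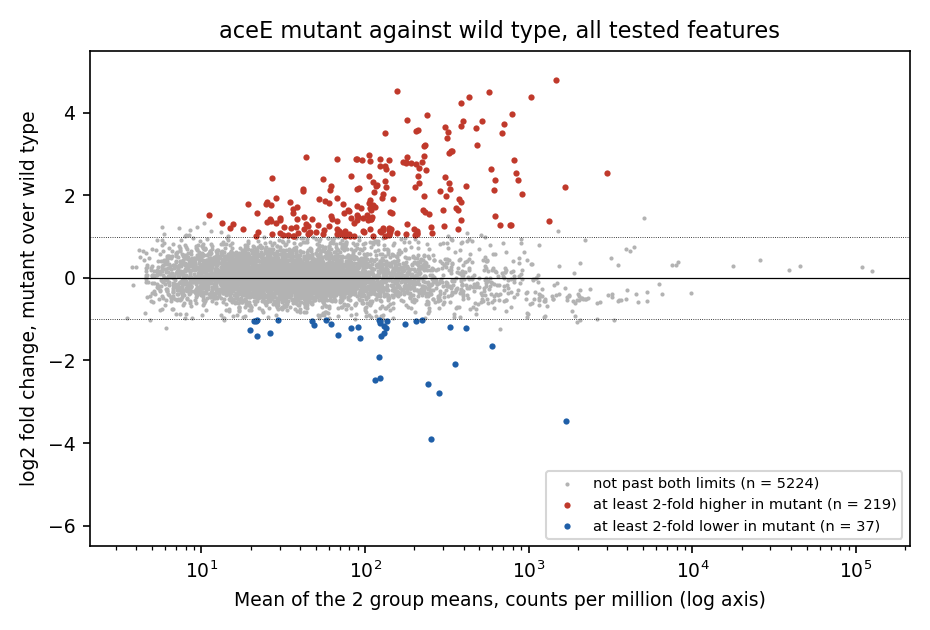
Log2 fold change of each tested feature (mutant over wild type, vertical axis) against its mean level in CPM (log axis). Red points are the 219 features at least 2-fold higher in the mutant, blue points the 37 at least 2-fold lower, both with adjusted p under 0.05, and dotted lines mark 2-fold.

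The direction of this imbalance held under the other scalings, but its size did not. Upper-quartile scaling moved the median log2 fold change of all features by -0.14 and gave 177 higher and 65 lower features at the 2-fold limit, a share of 73.1% higher. Scaling to total counts moved it by -0.13 and gave 178 higher and 60 lower, a share of 74.8%. Mutant replicate 1 and wild-type replicate 3 stood apart from the other libraries of their groups. Without these libraries, 557 features were higher and 466 lower at the adjusted p alone, while 196 were higher and 36 lower with the 2-fold limit. These libraries were left out because they deviated, which itself lowers the measured spread and raises the number of calls.

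The median level of the features that rose was 46.0 CPM in the wild type, against a median of 35.6 for all tested features, and 178 CPM in the mutant. Together the 219 risen features took 1.74% ± 0.25 of all counts in the wild type and 7.29% ± 1.21 in the mutant (SD, n = 3 each), with every mutant library (6.36 to 8.66%) above every wild-type library (1.46 to 1.95%). The 37 fallen features took 1.11% ± 0.28 of counts in the wild type and 0.278% ± 0.016 in the mutant. Both sets were selected on these libraries, so the shares describe their size and are not a separate test. The shares of the risen set also depend on which features are called, and in the wild type the share was 3.28% for the set called without wild-type replicate 3 and 1.11% for that called without mutant replicate 1. By mean level over all 6 libraries, the top 25% of features held 129 of the risen and 24 of the fallen features, and the bottom 25% held 8 and 2. No feature had under 3 counts in every library of one group and at least 10 in every library of the other.

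The feature with the largest rise was PGD38822998, at 103 ± 11.3 CPM in the wild type and 2844 ± 500.4 in the mutant (SD, n = 3 each). Its log2 fold change was 4.78 ± 0.46 (SE), a 27.5-fold rise, with an edgeR adjusted p of 7.23e-09. PGD38827728 rose from 13.1 ± 4.04 to 299 ± 65.4 CPM, a log2 fold change of 4.51 ± 0.33 (SE) or 22.8-fold, with an edgeR adjusted p of 1.33e-10. Its wild-type level rested on 19 to 32 counts per library.

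The largest falls were those of PGD38821828 and PGD38821830, which occupy consecutive rows of the table. PGD38821828 fell from 476 ± 231 CPM in the wild type to 31.7 ± 1.96 in the mutant (SD, n = 3 each), a log2 fold change of -3.90 ± 0.37 (SE) and an edgeR adjusted p of 5.10e-09. PGD38821830 fell from 3092 ± 1215 to 281 ± 30.1 CPM, a log2 fold change of -3.46 ± 0.46 (SE) and an edgeR adjusted p of 1.28e-06. Neither was silent in the mutant, where they had 52 to 71 and 452 to 605 counts per library. In both, wild-type replicate 3 had the highest level of the 3 wild-type libraries, at 739 and 4485 CPM.

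**Figure D2:**
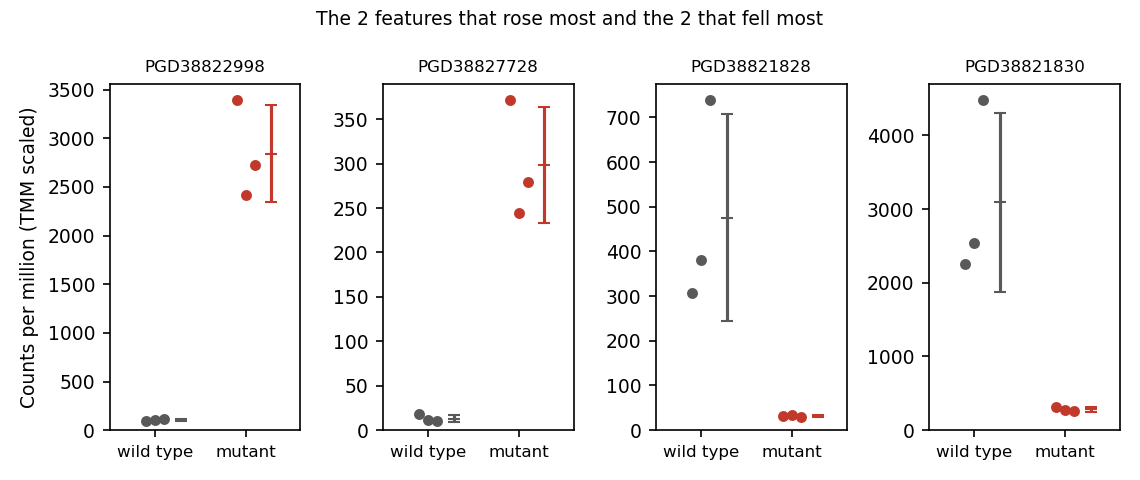
CPM of the 4 named features in each library (points, 3 per group) with the group mean and SD (bars beside the points). In every panel the 3 mutant libraries lie outside the range of the 3 wild-type libraries, which the rule for named features required.

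Changed features lay next to each other in the table far more often than in shuffled orders. The rows follow the identifiers, which rise in steps of 2, and the sources used here do not state whether this is the order along the chromosome. In 19 places, 4 or more consecutive rows all changed at least 2-fold in the same direction, and 17 of these runs were higher and 2 lower in the mutant. Shuffled row orders gave 0.014 such runs on average and at most 1 in 1000 shuffles (one-sided permutation p = 0.001, the smallest that they can give). The runs held 91 of the 219 risen features (41.6%) and 8 of the 37 fallen ones (21.6%). Across features, the log2 fold changes of adjacent rows correlated at r = 0.52, those 3 rows apart at 0.24 and those 10 rows apart at 0.080. These values include the shallow trend along the table described below. After subtraction of a running median along the rows, the adjacent-row correlation was still 0.48. No shuffled order gave an adjacent-row correlation beyond 0.042 in size. Features are not independent replicates, and these values describe this comparison only.

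The longest run held 9 features with a median rise of 3.55-fold, from a mean of 25.1 to 148 CPM. A run of 8 features contained PGD38822998 and had a median rise of 7.42-fold, with log2 fold changes between 2.36 and 4.78. Of the 2 runs of 7 features, one rose 4.94-fold and the other 6.59-fold at the median, and a run of 6 features rose 8.21-fold. The steepest run held 4 features that rose 19.9-fold at the median, from a mean of 56.5 to 994 CPM. Both falling runs held 4 features, with median falls of 2.31-fold and 2.32-fold. Leaving out both libraries that stood apart left 13 runs.

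A shallow trend also ran along the whole table. Features in the middle 50% of the rows had a median log2 fold change of 0.16, and those in the outer rows had a median of -0.093. The difference was 0.25 (95% block bootstrap interval 0.21 to 0.30), and the largest in 1000 shuffles of blocks of 50 rows was 0.10 (two-sided permutation p = 0.001, the smallest that they can give). This measure was chosen after the trend was seen, and the interval and p cover the spread between rows of these libraries, not between libraries. The difference was 0.18 without wild-type replicate 3, and the 6 libraries' own values, among them -0.0069 in mutant replicate 1 and -0.041 in wild-type replicate 1, gave an exact permutation p of 0.1, the smallest that 3 against 3 allows. The difference was 0.24 among the features that did not pass the test. Of the 64 features lower in the mutant at the adjusted p alone, 47 (73.4%) lay in the outer rows, which held 50.8% of all tested features. Without the libraries that stood apart, 401 of 466 did (86.1%). Of the features higher in the mutant, 131 of 286 (45.8%) lay in the outer rows, and 246 of 557 (44.2%) without those libraries. These shares restate the same fold changes and are no separate evidence for the trend. The libraries left out were chosen because they deviated, which itself lowers the measured spread and raises the number of calls.

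**Figure D3:**
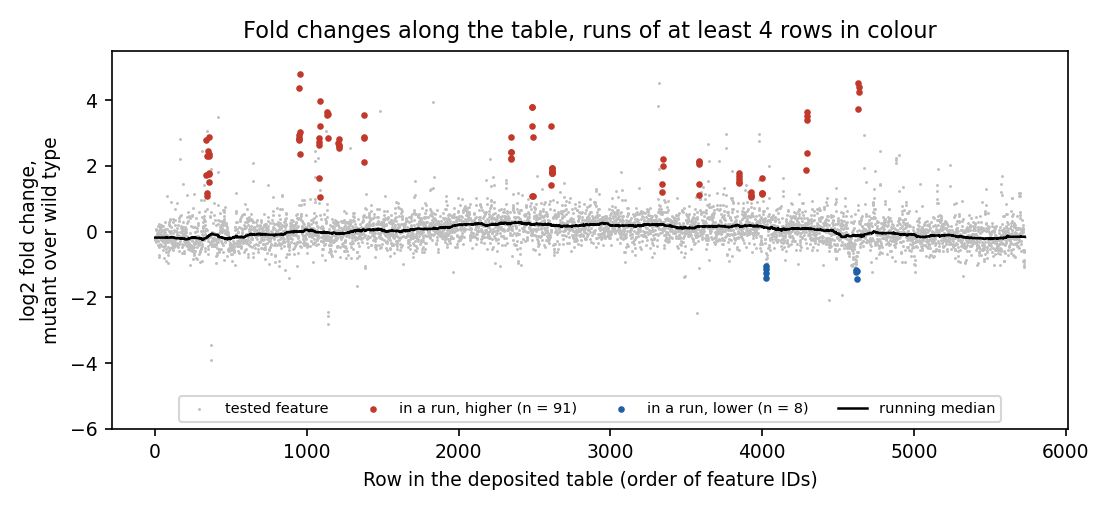
Log2 fold change of each tested feature (mutant over wild type) against its row in the table. Coloured points are the features in runs of at least 4 consecutive rows changed at least 2-fold (91 higher in red, 8 lower in blue), and the black line is a running median, which lies higher in the middle rows than at both ends.

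The libraries separated by group along the first principal component of log2 CPM, which held 46.7% of the variance. The second component held 36.4% and set mutant replicate 1 and wild-type replicate 3 apart from the other 4 libraries. After subtraction of each group's mean, the deviations of these libraries correlated at r = 0.66 across features. Library pairs within a group differed by more than counting noise, so none was treated as a repeat deposit of another. The chi-square per degree of freedom ran from 4.75 (mutant replicates 2 and 3) to 55.2 (wild-type replicates 1 and 3). It was 22.2 for wild-type replicates 1 and 2 and 18.4 for wild-type replicates 2 and 3, so it did not single out wild-type replicate 3. These values do not show whether the libraries came from separate cultures.

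**Figure D4:**
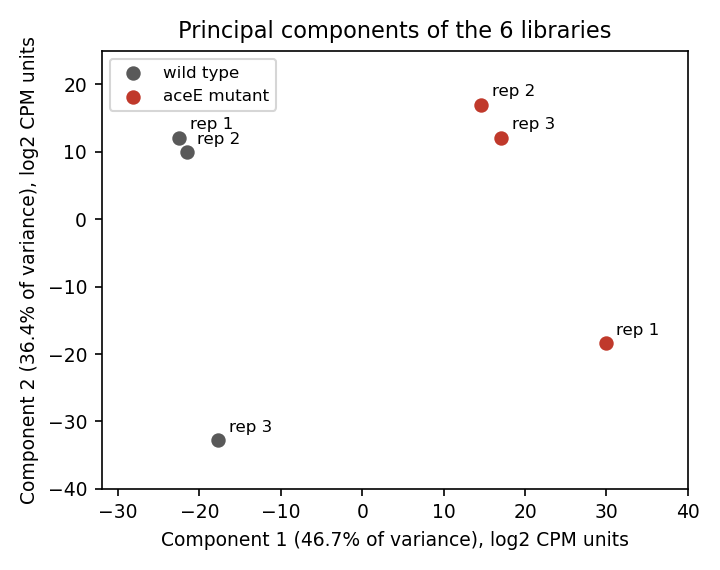
First 2 principal components of log2 CPM for the 6 libraries (grey, wild type; red, mutant). Component 1 parts the groups, and on component 2 mutant replicate 1 and wild-type replicate 3 lie below the other 4 libraries.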

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

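The 256 features, called at 2-fold without overlap, could hardly change sign, and none tested did in any refitted alternative. The 4 named ones passed the threshold in all 17 that gave them a value. The counts at the adjusted p alone moved most. Leaving out wild-type replicate 3 raised the changed features from 350 to 586 (470 higher, 116 lower), and over the 6 libraries left out in turn the counts ran from 254 to 586 in all, 191 to 470 higher and 29 to 116 lower, the lowest lower count without mutant replicate 3. With the 2-fold limit they ran from 214 to 297 in all, 162 to 274 higher and 23 to 52 lower, the lowest lower count without wild-type replicate 3. Leaving out both libraries that stood apart gave 1023 changed features (557 higher, 466 lower), and limma-voom with a quality weight per library gave 1103 (761 higher, 342 lower). Both settings remove or weigh down the libraries that deviated most, which itself raises the number of calls. These added settings included 343 and 350 of the 350 features, and at the 2-fold limit 203 and 219 of the 256. The fewest in any refitted alternative were 242 and 196, both without mutant replicate 1. The lower features numbered 141 with upper-quartile factors, 123 with the 50-count filter, 113 with total-count scaling and 29 of 233 at an adjusted p under 0.01. At the 2-fold limit, 65 were lower with upper-quartile factors and 60 with total-count scaling. A test against 2-fold itself left 111 features (103 higher, 8 lower), and a log2 limit of 1.5 left 138 (129 higher, 9 lower). Apart from the stricter limits and tests, the cause was not tested. Runs of 4 or more rows numbered 13 to 19, and those of 3 or more 26.

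The libraries' deviations did not follow the replicate numbers. Deviations of same-numbered libraries correlated at -0.53, 0.44 and -0.37, and mutant replicate 1 and wild-type replicate 3 each correlated best with the other. These libraries had the largest deviations of their groups, so the values cannot show whether the numbers mark paired cultures. With the replicate block, 281 features changed, 240 higher and 41 lower, and 212 were higher and 28 lower at the 2-fold limit. Of the 10 splits of the 6 libraries into 3 and 3, only the real one (1 of 10) gave any changed feature, 350 in all and 256 at the 2-fold limit, against 0 in the others with edgeR. At an unadjusted p under 0.05 the other splits gave 21 to 826 features and the real one 825, and the split with 826 put both libraries that stood apart with mutant replicate 3. So few splits cannot give a share under 0.05. The list tests, the level of aceE and the alternative without rRNA and tRNA were not run.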

Other observations

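The tests for swapped libraries, by wild-type level and by other splits of the samples were chosen after the result they measure was seen. All patterns below were found in these data before any explanation was tested.

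The trend along the rows was also measured in each library against the mean of all 6, so a difference between the groups must appear in these values. As the median log2 level of middle rows minus that of outer rows, each feature centred on its mean over the 6 libraries, it was -0.041, -0.054 and -0.26 in wild-type replicates 1, 2 and 3 and -0.0069, 0.20 and 0.16 in mutant replicates 1, 2 and 3. The group means were -0.12 ± 0.12 and 0.12 ± 0.11 (SD, n = 3 each). They mirror each other because of the centring, so only their difference of 0.24 carries information. The values of wild-type replicates 1 and 2 and mutant replicate 1 were the smallest in size. Within each group, the library that stood apart had the lowest value.

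An even background of reads would leave abundant features almost unmoved, but the difference between middle and outer rows in the 25% of features with the highest level was 98.4% of that in the 25% with the lowest (0.26 against 0.27). A single library was also not the whole source, since the difference was at least 0.18 without each library in turn, the lowest without wild-type replicate 3, and 0.23 without both libraries that stood apart. Chance placement of runs gave no difference as large in 1000 block shuffles, whose largest was 0.10 (permutation p = 0.001, the smallest they can give). The group remains open, as its libraries did not overlap but an exact permutation test of 3 against 3 cannot go below the p = 0.1 it gave. If the rows follow the chromosome from its replication origin, a candidate explanation is a lower copy number of genes near the origin in the mutant cultures, as slower growth would give; neither the order nor the growth rate was available to test it.

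Mutant replicate 1 and wild-type replicate 3 deviated from their groups in the same features (r = 0.66 over all tested features). Their higher total counts do not explain it, because the correlation was 0.64 after every library was thinned to 1835938 counts. An even background in the other 4 libraries does not either, as the correlation was 0.67 in the tenth of features with the highest level. A swap of the libraries is excluded by the 73 features changed at least 4-fold between the other 4 libraries, of which 100% lay nearer the library's own group in both. Their deviations were correlated between adjacent rows (0.40 and 0.44, against 0.14 to 0.32 in the other libraries). Their deviations were also the largest (SD 0.36 and 0.42 in log2, against 0.23 to 0.28), and counting noise weakens the correlation least where deviations are large. The contrast therefore points to no cause, and a difference in culture state or RNA handling was not tested. No label gives a batch, and no biological explanation was tested. Despite their higher totals, mutant replicate 1 and wild-type replicate 3 had the fewest features with at least 10 counts (5306 and 5273, against 5440 to 5519). Their lower-quartile counts were also the lowest (28 and 25, against 33 to 44). The 5 most abundant features took 30.0% of counts in mutant replicate 1 and 24.1% in wild-type replicate 3, the smallest share in each group. A larger share taken by these features therefore does not account for the low counts. Other differences in library quality or composition were not tested.

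More features rose than fell at the 2-fold limit, and neither technical explanation tested accounts for all of it there. At the adjusted p alone the imbalance was smaller in some settings, with 253 higher and 141 lower with upper-quartile factors and 557 and 466 without both libraries that stood apart. Leaving out libraries because they deviated itself raises the number of calls. Under 4 other scalings or centrings the share of higher features among those changed at least 2-fold was at least 73.1%. Missed falls among scarce features would restore the balance in abundant ones, but above the median of the mean level 180 rose and 30 fell (85.7%, exact 95% interval 80.2 to 90.1%), and above the median wild-type level, which the rise itself does not set, 138 rose and 32 fell (81.2%, interval 74.5 to 86.8%). In the 25% of features with the highest wild-type level the share was 67.8% (59 rose and 28 fell, interval 56.9 to 77.4%). Choosing features by a high wild-type level itself favours falls, so this share cannot decide whether a part of the imbalance rests on level. By mean level over all libraries, the shares were 80, 86.1, 89.5 and 84.3% from the lowest to the highest 25% of features. As a hypothesis, the imbalance at the 2-fold limit may belong to the mutation; other differences between the cultures, such as growth rate, were not tested.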
